A study of Homo sapiens with 8 samples.

How the data were processed

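Expression was measured on 8 arrays (GeneChip Human Genome U133 Plus 2.0, per the labels) of primary human keratinocytes: 2 with shRNAs against PRMT1 and 2 controls of that set, and 2 with shRNAs against CSNK1A1 and 2 controls of that set. The deposited values are log2 probe set values, made with RMA and R 2.11.1 per the submitters' processing notes; whether RMA was run over all arrays at once or per set of 4 is not stated there. The genome build was not given in the sources used here. The table held 54675 probe sets, 62 of them control probe sets, with no missing value, and its normalization was kept.

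From the deposited log2 values, 1 probe set per gene was taken. Of the probe sets, 41097 named 1 gene symbol, 1801 several and 11777 none, and those with 1 symbol were used; for 41037 of them the symbol was found in the gene table. The probe set with the highest mean over the 8 arrays stood for its gene (10499 genes had more than 1), which gave 19724 genes. TP63 had no probe set with a single symbol and was not analysed here. XIST and Y-linked genes were left out throughout, and HLA genes were left out of the named genes.

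The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 4 group means, equal array weights, 4 residual and 4.24 prior degrees of freedom), and a gene passed at a Benjamini-Hochberg adjusted p under 0.05. All 8 arrays shared 1 estimate of the spread per gene because each group held 2. Contrasts were each knockdown against the controls of its set, the CSNK1A1 effect minus the PRMT1 effect, and the control sets against each other. Of the last, no gene is named as past the threshold. Overlaps were tested with Fisher's exact test over genes. Standard errors are those of the fit, which assumes the same spread in all 4 groups. An SE given here can therefore be too large or too small for its own 4 arrays. For PRMT1 in its own knockdown it was 0.84, and 0.11 with the 4 arrays of the set alone. For CSNK1A1 in its own knockdown it was 0.15, and 0.17 with the 4 arrays of the set alone. A fold change is that of the RMA values, and SD is the spread of the arrays of a group.

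Gene lists (18 lists and 4 lists of cell type markers, 587 genes, of which 527 were measured) were tested with camera at a preset correlation of 0.01 and adjusted over the 22 lists of a comparison, with an estimated correlation and with fry as alternatives. Member counts were made over all genes and adjusted over the list alone. The comparisons, tests, lists, alternatives and the rule for named genes were chosen before the data were examined. That rule took the target, the 10 largest changes in each direction among genes past the threshold whose hairpins lay on the same side of both controls, up to 4 members per list, 12 genes given always, up to 10 shared and 5 opposite genes, and the 5 largest differences in each direction. Counts without the CSNK1A1 hairpin A array beside list counts, the 4 control arrays without a replicate block, and the gene families of the closing section were chosen after the data were seen.

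Alternatives were a trend in the prior, a robust fit, a filter on dim genes, quantile normalization, median centring, other ways to sum probe sets, array weights, the 4 arrays of a set alone, other thresholds and leaving out each array in turn. The fit was tested on simulated data for the PRMT1 comparison, with 200 of 19724 genes changed: 45% of those changed by a log2 value of 1 and 89% of those changed by 2 passed, and 2.19% of the 137 calls were false. Of 150 genes planted as changed in both comparisons, 71 passed in both with the same direction. The simulated genes varied independently, with the same spread in all groups. Correlated genes and an array that stands apart were not simulated, so these rates may not hold for the real arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.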

Results

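The data were gene expression profiles of primary human keratinocytes, the main cell type of the epidermis, grown at 1.2 mM calcium, a level at which these cells differentiate. A retroviral vector carried short hairpin RNAs (shRNAs) against PRMT1 or against CSNK1A1, or control shRNAs. PRMT1 is the main enzyme that places asymmetric dimethyl marks on arginine, and CSNK1A1 encodes casein kinase 1 alpha, a kinase that takes part in the breakdown of beta-catenin. The 8 arrays formed 4 groups of 2: the PRMT1 knockdown (hairpins A and B), its controls 1 and 2, the CSNK1A1 knockdown (hairpins A and B) and its controls 1 and 2. The design text asks what loss of each gene does to gene expression, and the series title places both genes in the upkeep of epidermal progenitors. The values were log2 RMA values, whose medians lay between 5.23 and 5.31 on the 8 arrays. The number of arrays limits the precision. The 2 arrays of a knockdown group carried different hairpins, so their spread includes any difference between the hairpins. For the controls, nothing in the labels says whether the 2 arrays came from separate cultures, so their spread can be technical. The p-values measure only the spread between these samples.

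The targeted genes were low in the arrays that carried their hairpins. PRMT1 averaged 12.74 ± 0.04 (SD, n = 2) in its controls and 10.15 ± 0.11 (SD, n = 2) in the PRMT1 knockdown, a 6.04-fold lower level (log2 fold change -2.59 ± 0.84 SE). CSNK1A1 averaged 12.48 ± 0.02 (SD, n = 2) in its controls and 10.05 ± 0.18 (SD, n = 2) in the CSNK1A1 knockdown and fell by 2.43 on the log2 scale, or 5.38-fold (SE 0.15, limma adjusted p = 0.00015). As the mean of their probe sets, PRMT1 was at -1.41 in its knockdown and CSNK1A1 at -1.28 in its own. CSNK1A1 had a log2 fold change of -0.03 ± 0.15 SE in the PRMT1 knockdown (adjusted p = 0.96). Of the 11 CSNK1A1 probe sets above the median brightness, 6 passed the threshold as lower, and the log2 fold changes of all 11 ran from -2.64 to -0.14. PRMT1 did not pass the threshold in its own knockdown over all 8 arrays (adjusted p = 0.16), because the spread shared by the groups holds an array of the other set: PRMT1 read 8.65 with CSNK1A1 hairpin A and 12.004 with CSNK1A1 hairpin B. With the 4 arrays of the PRMT1 set alone its adjusted p was 0.016, with array weights it was 0.0021, and without the CSNK1A1 hairpin A array, or without the CSNK1A1 hairpin B array, it was 0.00067.

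**Figure D1:**
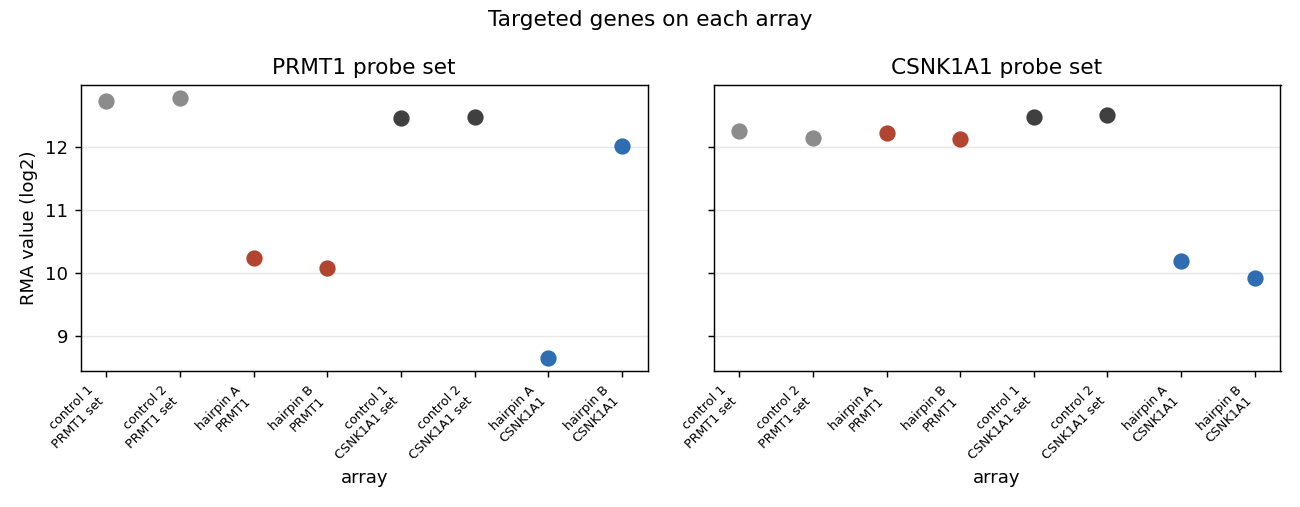
RMA value (log2) of the PRMT1 probe set (left) and the CSNK1A1 probe set (right) on each of the 8 arrays, 1 point per array, with the PRMT1 knockdown in red, the CSNK1A1 knockdown in blue and controls in grey. Both PRMT1 hairpins lie near 10.15 for PRMT1 against 12.74 in their controls, and the CSNK1A1 hairpin A array is at 8.65 for PRMT1.

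The CSNK1A1 hairpin A array stood apart from the other 7 in its control probe sets. The GAPDH probe set at the 5′ end read 3.70 log2 units below that at the 3′ end (-3.70), against -0.24 to -0.07 on the other 7 arrays, and the ACTB pair differed by -3.54 against -1.56 to -0.70. Its correlation with CSNK1A1 hairpin B over all probe sets was 0.975, against 0.993 between the PRMT1 hairpins. Relative to CSNK1A1 hairpin B, this array differed by -3.44, -2.25 and 0.02 at the 5′, middle and 3′ probe sets of GAPDH. For ACTB these values were -3.61, -2.18 and -1.62, so the deficit was largest at the 5′ end. The labels name a whole-transcript labelling kit beside this 3′ array design, so which labelling was used is open. The difference is given as measured. This array enters the CSNK1A1 group and, through the shared spread, every test, so gene counts without it, and list counts that it moves most, are given below.

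**Figure D2:**
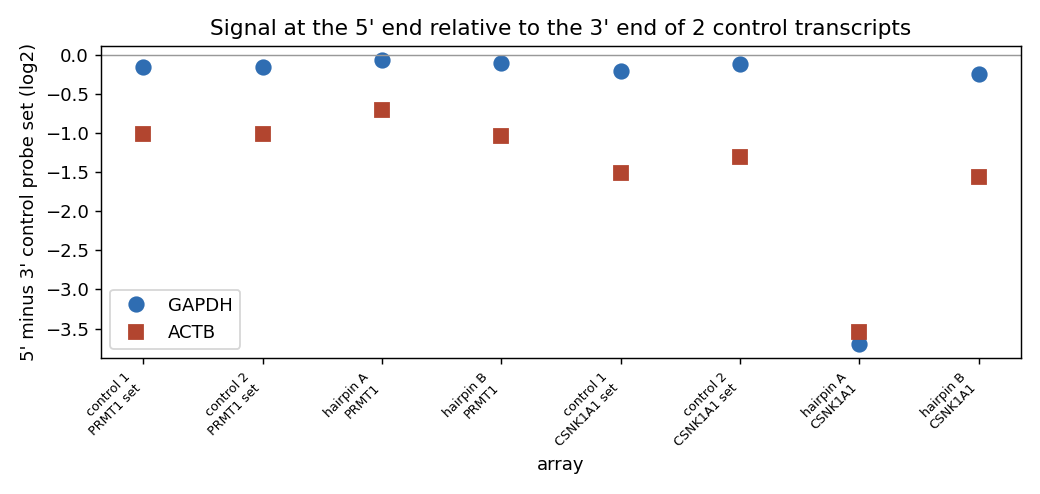
Difference between the 5′ and the 3′ control probe set (log2) of GAPDH (blue circles) and ACTB (red squares) on each array. The CSNK1A1 hairpin A array is at -3.70 and -3.54, below the other 7 arrays.

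Over 19724 genes, 285 rose and 241 fell past the threshold with PRMT1 knockdown against the controls of the set. CXCL14, a skin chemokine, rose 62.4-fold (log2 fold change 5.96 ± 0.35 SE, n = 2 against 2, adjusted p = 0.0010). The neurofilament genes NEFL and NEFM rose by 4.57 ± 0.33 and 3.26 ± 0.38 (SE), the matrix metalloproteinase MMP3 by 4.09 ± 0.24 and the complement protease C1R by 3.53 ± 0.32. IGFL1, KANK4, IGFBP3, KRT75 and ACKR3 complete the 10 largest increases, between 3.20 and 4.46. Among genes past the threshold over all 8 arrays, which PRMT1 itself (-2.59) was not, the largest decrease was that of CIDEA, a lipid droplet protein (-2.13 ± 0.26, adjusted p = 0.013), followed by MTFR2, HS3ST2, the kinetochore gene SPC25, SGO1, E2F8, GIRGL, CLSPN, DEPDC1 and the sodium channel subunit SCNN1A, between -1.85 and -1.58. Over these 526 genes the median absolute change was 0.92 for hairpin A and 1.31 for hairpin B.

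Of the 40 measured interferon-response genes, 10 rose and none fell in the PRMT1 knockdown (20 rose and 2 fell adjusted over the list alone), with a median log2 fold change of 0.58. CXCL11 (3.11 ± 0.24 SE), CXCL10 (2.86 ± 0.42), IFIT2 (2.40 ± 0.31) and the tethering protein BST2 (2.29 ± 0.18) led, and the list passed camera's test (adjusted p = 1.63e-12, and adjusted p = 0.028 with an estimated correlation). Without the CSNK1A1 hairpin A array the interferon list had adjusted p = 0.067 with an estimated correlation. Among 30 inflammatory cytokine and NF-kappaB genes 5 rose (14 rose and 1 fell over the list alone), including IL20 (2.40 ± 0.23), IL33 (2.16 ± 0.27) and IL24 (2.13 ± 0.17). That list had adjusted p = 1.31e-09 and adjusted p = 0.11 with an estimated correlation. Of 26 genes of the matrix and TGF-beta list 5 rose (8 over the list alone), with MMP3, MMP9 (2.36 ± 0.24), the matrix protein TNC (1.98 ± 0.26) and MMP10 (1.57 ± 0.17). Its test gave adjusted p = 1.75e-06 and adjusted p = 0.056 with an estimated correlation. Of 22 stress keratins and alarmins 8 rose (13 over the list alone), among them IL36G (2.25 ± 0.35), SERPINB13 (2.14 ± 0.41), KRT16 (1.80 ± 0.32) and the antimicrobial RNASE7 (1.63 ± 0.22). The test of these alarmins gave adjusted p = 2.98e-10 and adjusted p = 0.11 with an estimated correlation.

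Of 18 spinous genes 6 rose with PRMT1 knockdown (9 rose and 1 fell over the list alone), with the desmosomal cadherin DSG1 at 1.40 ± 0.19 (SE), LY6D at 1.34 ± 0.24, SBSN at 1.16 ± 0.23 and KRTDAP at 1.07 ± 0.14. The spinous list had adjusted p = 1.16e-07 and adjusted p = 0.056 with an estimated correlation. Of 33 cornified envelope and late genes 5 rose and 1 fell (9 and 1 over the list alone). Involucrin, IVL, rose by 1.76 ± 0.19, CRCT1 by 1.54 ± 0.26 and SPRR1A by 1.24 ± 0.16, while the envelope plakin PPL fell (-1.15 ± 0.15). The cornified list had adjusted p = 1.16e-05 and adjusted p = 0.056 with an estimated correlation. KRT1 (0.80 ± 0.17, adjusted p = 0.051) and the transcription factor gene GRHL3 (1.06 ± 0.23, adjusted p = 0.053) missed the threshold. So did ZNF750 (0.33 ± 0.24), KLF4 (0.25 ± 0.13), KRT10 (-0.39 ± 0.14), AXIN2 (0.22 ± 0.19) and CDKN1A (0.57 ± 0.16, adjusted p = 0.11). The basal keratins KRT5 (0.10 ± 0.16) and KRT14 (0.13 ± 0.13) did not pass either. KRT1 averaged 4.38 in the controls and 5.17 in the PRMT1 knockdown, both below the median of 5.27 over all probe sets. DSG1 averaged 4.35 and 5.75, so the changes of KRT1 and DSG1 are between dim values and less certain. LY6D, SBSN and KRTDAP were brighter, at 6.69, 7.08 and 8.12 in the controls. Without the CSNK1A1 hairpin A array, which is in neither PRMT1 group, KRT1 (adjusted p = 0.022), GRHL3 (0.026) and CDKN1A (0.035) passed. Among 28 differentiation transcription factors, MAF rose (2.98 ± 0.41) and no other passed (2 over the list alone; list adjusted p = 0.00071, adjusted p = 0.18 with an estimated correlation). Of 26 basal progenitor genes, IGFBP3 (3.43 ± 0.33) and the matrix protein POSTN (2.83 ± 0.49) rose and NRG1 fell (-1.10 ± 0.21), with 4 and 2 over the list alone and list adjusted p = 0.24.

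Of 40 mitosis genes 13 fell and none rose with PRMT1 knockdown (38 fell over the list alone), with a median log2 fold change of -1.03. The proliferation marker MKI67 fell by 1.51 (SE 0.16), the kinetochore gene NUF2 by 1.46 (SE 0.21), KIF11 by 1.27 (SE 0.22) and BUB1 by 1.25 (SE 0.24). Of 42 DNA replication genes 15 fell (33 over the list alone; median -0.98), including CLSPN (-1.60 ± 0.26), MCM10 (-1.54 ± 0.30), CCNE2 (-1.53 ± 0.25) and GINS2 (-1.40 ± 0.22). The lists had adjusted p = 2.23e-29 and 1.00e-24, and both had adjusted p = 0.16 with an estimated correlation. That correlation was 0.72 for mitosis and 0.53 for replication, far above the preset 0.01. With fry both had adjusted p = 0.027. Fry gave adjusted p = 0.0053 for the spinous, cornified and matrix lists, 0.017 for the inflammatory and 0.019 for the alarmin list.

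Other lists were also examined. In the p53 list of 30 genes TP53INP1 rose (1.48 ± 0.19 SE; 7 over the list alone) and the median was 0.30 (adjusted p = 1.50e-05, adjusted p = 0.056 with an estimated correlation). As lists, 3 passed the test in the lower direction with no member past the threshold over all genes. They were cholesterol synthesis (-0.22, 19 genes, adjusted p = 0.0031, adjusted p = 0.18 with an estimated correlation) and RNA-binding substrates of arginine methylation (-0.21, 22 genes, adjusted p = 0.014, adjusted p = 0.37 with an estimated correlation). Arginine methyltransferases, PRMT1 among them, were the other list (-0.24, 12 genes, adjusted p = 0.020, adjusted p = 0.44 with an estimated correlation). Part of the shift of this last list was set by the knockdown itself, since it holds PRMT1 (-2.59). With fry these 3 lists did not pass, at adjusted p = 0.078, 0.18 and 0.22 in this order. Without PRMT1 hairpin B the last 2 had adjusted p = 0.16 and 0.052, and without control 2 of the PRMT1 set the methyltransferases had adjusted p = 0.057. NUPR1 rose (2.58 ± 0.29) in the integrated stress response list, which had adjusted p = 0.62 over 29 genes. Lipid and barrier synthesis (24 genes, adjusted p = 0.53), Wnt targets (23 genes, adjusted p = 0.52) and casein kinases (8 genes, adjusted p = 0.51) had no member past the threshold and, as lists, did not pass. For Wnt targets and casein kinases the median had the opposite sign to the test and to the mean. Of 19 fibroblast markers FBN1 (1.80 ± 0.26), DCN (1.40 ± 0.16), S100A4 (0.98 ± 0.18) and FAP (0.80 ± 0.16) rose, beside the matrix genes above. Over the list alone 7 rose and 2 fell (adjusted p = 0.0040, adjusted p = 0.18 with an estimated correlation). Markers of melanocytes (adjusted p = 0.95), endothelium (0.52) and immune cells (0.53) had no member past the threshold.

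The PRMT1 counts depended on which arrays set the spread. Without CSNK1A1 hairpin A, or without CSNK1A1 hairpin B, 1078 genes rose and 1090 fell. All 526 genes above were among them when hairpin A was left out, with 24 interferon, 39 mitosis, 35 replication, 11 spinous and 13 cornified genes past the threshold in the direction of the list. In that fit 10 inflammatory, 14 alarmin, 9 matrix, 8 p53, 6 basal and 7 fibroblast genes rose and 2 fibroblast, 2 basal, 2 cholesterol, 2 Wnt and 2 methyltransferase genes fell. In the casein kinase list 2 rose. Without control 1 or 2 of the PRMT1 set 4 and 5 genes rose and 0 fell, without PRMT1 hairpin B 21 rose and 0 fell, and without control 1 or 2 of the CSNK1A1 set 43 rose and 8 fell. Of the 67 named genes past the threshold, 3 stayed past it without either control of the PRMT1 set, 58 without PRMT1 hairpin A, 12 without PRMT1 hairpin B and 23 without either control of the CSNK1A1 set. At an unadjusted p under 0.05 limma counted 1020 lower genes without control 1, 1004 without control 2 and 839 without hairpin B of the PRMT1 set.

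**Figure D3:**
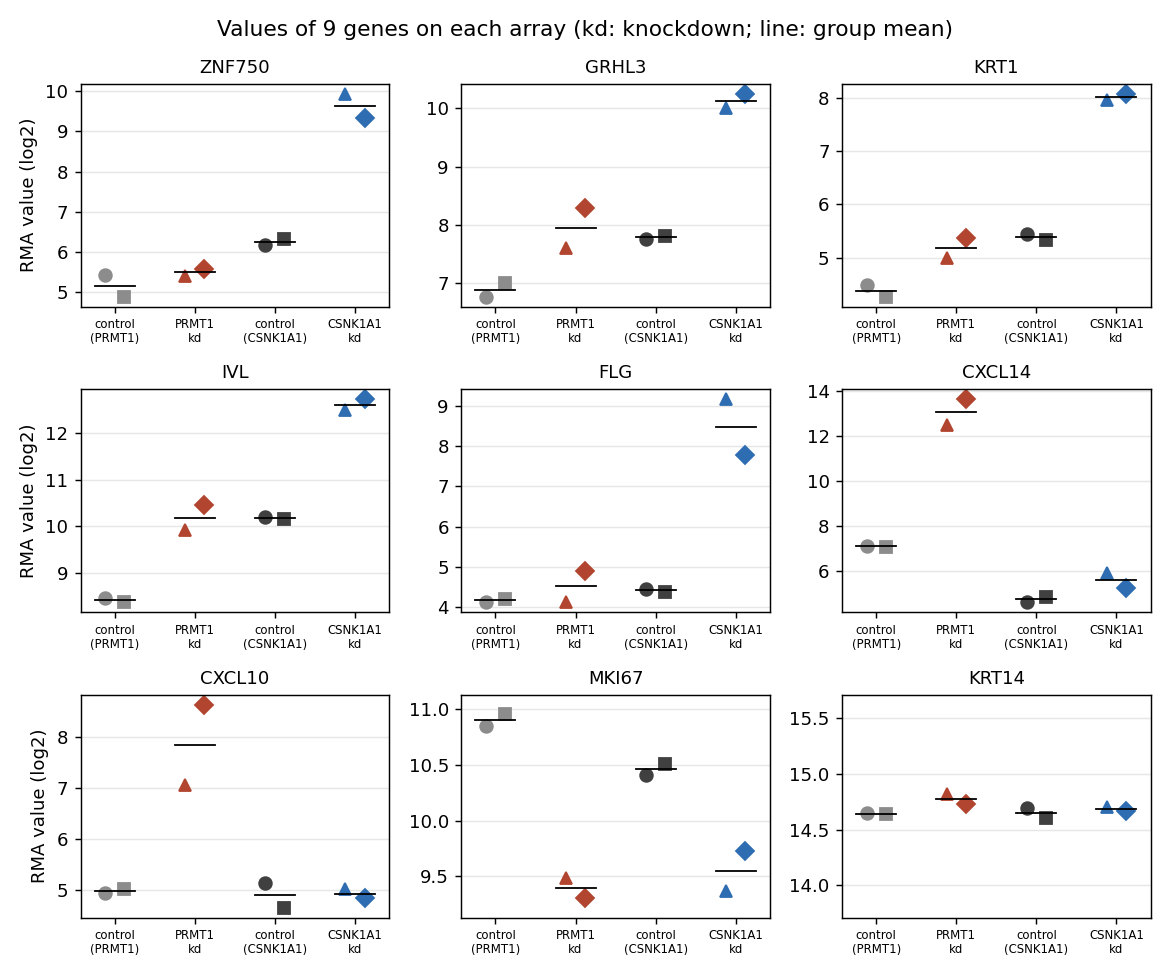
RMA values (log2) of 9 genes on the 8 arrays, with circles and squares for controls 1 and 2, triangles and diamonds for hairpins A and B, and a line at each group mean, where each panel has its own vertical range of at least 2 log2 units. ZNF750, GRHL3, KRT1, IVL and FLG are highest in the CSNK1A1 knockdown, CXCL14 and CXCL10 in the PRMT1 knockdown, and MKI67 is lower in both knockdowns than in their controls.

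Against the controls of the set 611 genes rose and 439 fell with CSNK1A1 knockdown. The calcium-binding protein gene S100P rose 32.6-fold (log2 fold change 5.03 ± 0.18 SE, n = 2 against 2, adjusted p = 3.5e-05), and KRT23 by 4.65 ± 0.25. The adhesion molecule CEACAM6 rose by 4.34 ± 0.27, the small heat shock protein HSPB8 by 4.33 ± 0.31, S100A7 by 4.28 ± 0.23 and filaggrin, FLG, by 4.04 ± 0.41. LINC00520, CYP1B1, SPINK7 and LCE3D complete the 10 largest increases, between 3.78 and 4.20. After CSNK1A1 itself, the largest decreases were those of the immunoproteasome subunit PSMB9 (-2.14 ± 0.16), MND1, the replicative helicase subunit MCM2 (-2.07 ± 0.35), PSRC1, CCBE1, DPYD, MCM10, the mitotic transcription factor FOXM1 (-1.81 ± 0.38) and NCAPH (-1.78 ± 0.35). Over these 1050 genes the median absolute change was 1.17 for hairpin A and 0.92 for hairpin B.

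Of 33 cornified envelope and late genes 21 rose and none fell in the CSNK1A1 knockdown (25 over the list alone), with a median log2 fold change of 1.73. FLG and LCE3D led, with the protease inhibitor CST6 (3.50 ± 0.25 SE) and cornifelin, CNFN (3.28 ± 0.13), and IVL rose by 2.42 ± 0.19. The list had adjusted p = 1.45e-26 and adjusted p = 0.0097 with an estimated correlation. Of 18 spinous genes 9 rose (12 over the list alone; median 1.76), among them KRT23, KRTDAP (3.47 ± 0.14), SBSN (3.23 ± 0.23), DSG1 (3.21 ± 0.19) and KRT1 (2.63 ± 0.17). KRT10 was at 0.24 ± 0.14 (adjusted p = 0.35), and the spinous list had adjusted p = 1.97e-15 and adjusted p = 0.029 with an estimated correlation. Of 28 differentiation transcription factors 10 rose (16 over the list alone), including ZNF750 (3.39 ± 0.24), RORA (2.98 ± 0.37), HOPX (2.88 ± 0.15), GRHL1 (2.48 ± 0.18), GRHL3 (2.34 ± 0.23) and KLF4 (0.85 ± 0.13). This list had adjusted p = 6.07e-13 and adjusted p = 0.032 with an estimated correlation. Of 24 lipid and barrier genes 5 rose (10 over the list alone), with the lipid transporter ABCA12 at 2.95 ± 0.17, SULT2B1 at 2.29 ± 0.25, ALOX12B at 1.78 ± 0.26 and ELOVL4 at 1.53 ± 0.22. Its test gave adjusted p = 7.16e-06 and adjusted p = 0.029 with an estimated correlation. Of 22 stress keratins and alarmins 14 rose (15 rose and 1 fell over the list alone; median 1.65), led by S100P, S100A7, the defensin DEFB1 (3.61 ± 0.31) and LCN2 (3.46 ± 0.43). The alarmin list had adjusted p = 1.26e-15 and adjusted p = 0.053 with an estimated correlation.

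Of 40 mitosis genes 28 fell with CSNK1A1 knockdown (40 over the list alone; median -1.10), including FOXM1, KIF20A (-1.55 ± 0.24 SE), PRC1 (-1.46 ± 0.27), TPX2 (-1.45 ± 0.33) and MKI67 (-0.91 ± 0.16). Of 42 replication genes 19 fell (1 rose and 36 fell over the list alone; median -0.99), including MCM2, MCM10 (-1.83 ± 0.30), CDC45 (-1.60 ± 0.36) and MCM5 (-1.43 ± 0.22). The lists had adjusted p = 1.45e-26 and 7.66e-20, and both had adjusted p = 0.16 with an estimated correlation. With fry they had adjusted p = 0.019 and 0.021, and the alarmin list had 0.0010. Of 30 p53 targets 11 rose (17 over the list alone; median 0.54), with TP53INP1 at 1.99 ± 0.19, GDF15 at 1.27 ± 0.21, ZMAT3 at 1.26 ± 0.17 and SPATA18 at 1.26 ± 0.17. The p53 list had adjusted p = 1.00e-07 and adjusted p = 0.029 with an estimated correlation, and CDKN1A was at 0.46 ± 0.16 (adjusted p = 0.14). Of 29 integrated stress response genes 8 rose (13 over the list alone), led by NUPR1 (1.89 ± 0.29), VLDLR (1.45 ± 0.19), the transcription factor DDIT3 (1.42 ± 0.14) and CHAC1 (1.16 ± 0.16). That list had adjusted p = 0.0019 and adjusted p = 0.055 with an estimated correlation, and adjusted p = 0.21 without hairpin B.

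With CSNK1A1 knockdown 6 of 40 interferon-response genes fell and none rose (2 rose and 18 fell over the list alone; median -0.44), with OAS3 (-1.20 ± 0.25 SE), EPSTI1 (-1.16 ± 0.15), USP18 (-0.76 ± 0.17) and IFI44 (-0.74 ± 0.13). The genes that led the list with PRMT1 knockdown did not pass here (CXCL11 -0.01 ± 0.24, CXCL10 0.03 ± 0.42, IFIT2 0.69 ± 0.31), and OAS3 was at -0.70 ± 0.25 with PRMT1 knockdown. The interferon list had adjusted p = 4.90e-06 and adjusted p = 0.029 with an estimated correlation. Of 22 RNA-binding methylation substrates HNRNPD (-0.85 ± 0.17) and HNRNPA3 (-0.74 ± 0.13) fell (10 over the list alone; adjusted p = 2.24e-06, adjusted p = 0.15 with an estimated correlation). Lists that did not pass as a whole held single movers. In the inflammatory list (30 genes, adjusted p = 0.16) CXCL5 (-1.76 ± 0.34), CXCL2 (-0.97 ± 0.14) and IL23A (-0.68 ± 0.15) fell and PTGS2, the inducible prostaglandin synthase, rose (1.58 ± 0.17), with 1 and 4 over the list alone. In the matrix list (26 genes, adjusted p = 0.97, 3 up and 3 down, 5 and 5 over the list alone) MMP10 (2.43 ± 0.17), MMP1 (2.03 ± 0.14) and TAGLN (1.65 ± 0.29) rose and SPARC fell (-1.70 ± 0.14). Among basal progenitor genes (26 genes, adjusted p = 0.41, 2 up and 3 down over the list alone) POSTN (3.46 ± 0.49) and KRT15 (1.37 ± 0.23) rose and the Notch ligand DLL1 (-1.68 ± 0.20) and LRIG1 (-1.07 ± 0.14) fell. KRT5 was at -0.24 ± 0.16 and KRT14 at 0.03 ± 0.13, a value whose sign turns (-0.01) when arrays are centred on their medians. Of 23 Wnt targets KREMEN1 fell (-0.74 ± 0.14, 1 over the list alone), and the list had adjusted p = 0.97. AXIN2, a direct target of beta-catenin, was at 0.16 ± 0.19 (adjusted p = 0.70). It averaged 5.64 in the controls and 5.79 in the knockdown, near the median of 5.27 over all probe sets, where a change may be missed. PRMT6 fell (-1.66 ± 0.39, or -0.92 without hairpin A) among 12 arginine methyltransferases (1 over the list alone). This list had adjusted p = 0.15 and adjusted p = 0.57 with an estimated correlation. Its median was -0.17, or -0.30 without hairpin B, where PRMT1, a member, was at -3.81 on the hairpin A array. CSNK1A1 was the single casein kinase past the threshold over all genes (8 genes, 1 up and 1 down over the list alone, list adjusted p = 0.23). For the Wnt and matrix lists the median and the test differed in sign. Cholesterol synthesis (19 genes, adjusted p = 0.15, adjusted p = 0.47 with an estimated correlation) had no member past the threshold over all genes. Neither did melanocyte (adjusted p = 0.16, adjusted p = 0.31 with an estimated correlation, 3 up over the list alone), endothelial (adjusted p = 0.83) and immune cell markers (adjusted p = 0.69). The cholesterol median was -0.14 with and without hairpin B, and the melanocyte median was 0.02, or 0.16 without hairpin A. Camera's test of the cholesterol, fibroblast and methyltransferase lists changed side of the threshold, to passing, without hairpin B. That of the melanocyte list did so without hairpin A. With fry over all arrays melanocyte markers had adjusted p = 0.033. Casein kinases, which hold CSNK1A1 itself, had adjusted p = 0.00094 with fry. Of 19 fibroblast markers S100A4 rose (1.26 ± 0.18, 2 over the list alone). The fibroblast list had adjusted p = 0.15 and adjusted p = 0.46 with an estimated correlation, and its median was 0.19, or 0.35 without hairpin B.

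Without the CSNK1A1 hairpin A array 701 genes rose and 526 fell, of which 508 and 309 were among those above. Past the threshold in the direction of the list were 26 cornified, 12 spinous, 8 lipid and barrier, 10 transcription factor, 10 p53, 17 mitosis and 15 replication genes, and 4 inflammatory, 4 basal and 2 fibroblast genes rose. With an estimated correlation the cornified list then had adjusted p = 0.040 and the spinous list 0.078. The lipid and barrier, transcription factor, p53 and interferon lists then each had adjusted p = 0.052 with an estimated correlation. Named genes whose fold change moved by over 1.5 times without that array were MND1 (to -1.30), FOXM1 (-1.14), PRMT6 (-0.92), CCBE1 (-2.66), POSTN (2.55), SERPINB13 (2.46), FLG (3.35), CYP1B1 (3.43), RORA (2.30) and LCN2 (4.28). The genes MCM2 (-1.48), NCAPH (-1.23) and PSRC1 (-1.33) moved by less than that. The genes PRC1, TPX2, CDC45 and IL23A did not pass without that array. Of the 87 named genes past the threshold, 67 stayed past it without either control of the PRMT1 set, 79 without either PRMT1 hairpin, 38 without either control of the CSNK1A1 set and 83 without CSNK1A1 hairpin A. The counts were 2868 and 3193 without hairpin B, 140 and 9 without control 1 of this set, and 158 and 9 without control 2. They were 331 and 113 without either control of the PRMT1 set and 156 and 24 with the 4 arrays of the set alone.

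**Figure D4:**
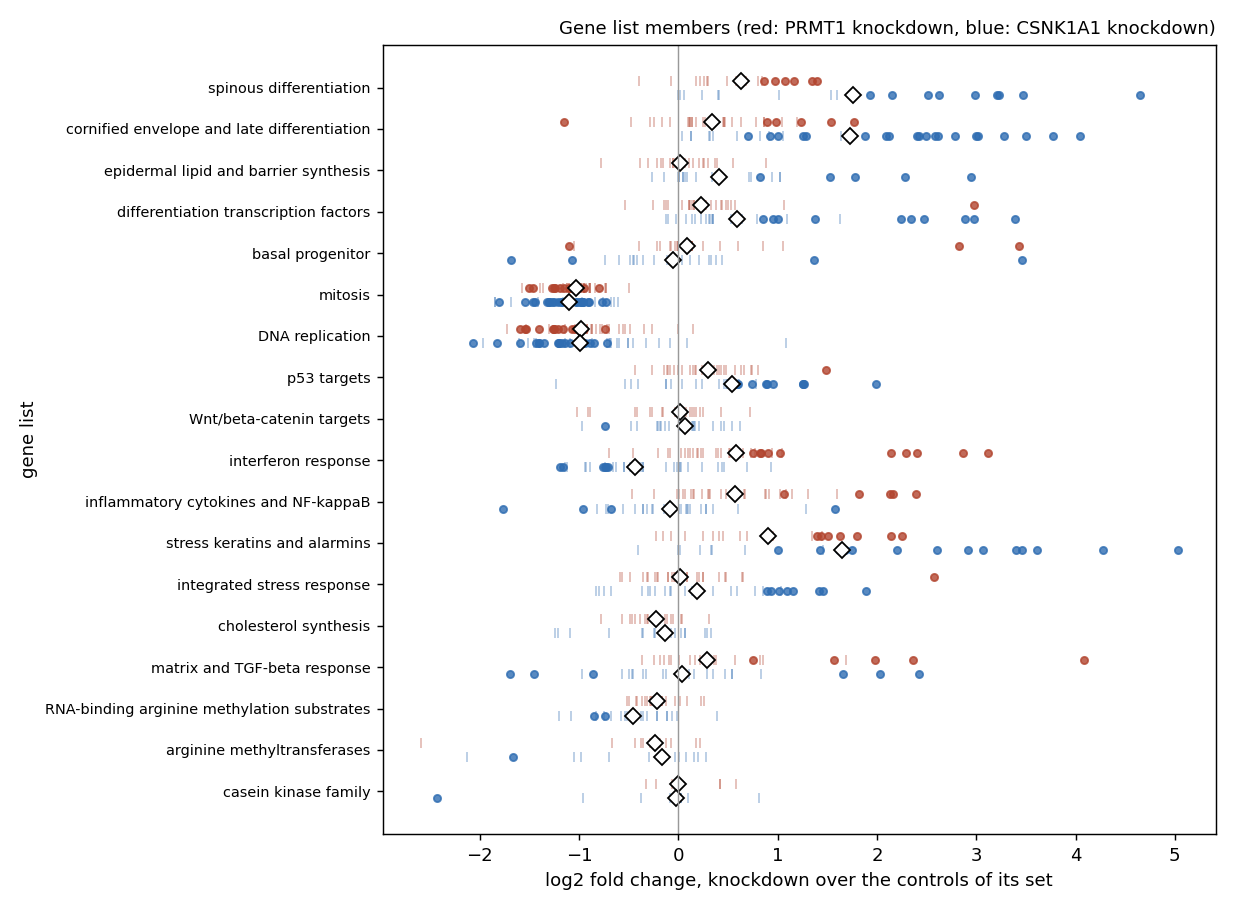
Log2 fold changes of the members of 18 gene lists in the PRMT1 knockdown (red, upper row of each list) and the CSNK1A1 knockdown (blue, lower row); filled points passed an adjusted p of 0.05, ticks did not, and open diamonds are list medians. The cornified median is 0.34 for PRMT1 and 1.73 for CSNK1A1, the mitosis medians are -1.03 and -1.10, and the interferon medians are 0.58 and -0.44.

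The effects of the 2 knockdowns were compared gene by gene. The CSNK1A1 effect was above the PRMT1 effect for 104 genes and below it for 47. KRT23 (difference of log2 fold changes 4.36 ± 0.35 SE), CEACAM6 (4.33 ± 0.39), S100P (4.11 ± 0.25), the protease inhibitor SPINK7 (3.71 ± 0.31) and FLG (3.70 ± 0.58, or 3.01 without CSNK1A1 hairpin A) had the largest excess with CSNK1A1 knockdown. CXCL14 (-5.12 ± 0.50), IGFBP3 (-3.85 ± 0.46), MMP9 (-3.81 ± 0.34), MMP3 (-3.55 ± 0.34) and C1R (-3.45 ± 0.45) had the largest excess with PRMT1 knockdown. All 10 had adjusted p between 0.0030 and 0.032. As lists, the cornified (median difference 1.08, 9 members past the threshold, 22 over the list alone, adjusted p = 2.62e-21, adjusted p = 0.0077 with an estimated correlation) rose more with CSNK1A1 knockdown. So did the spinous (1.06, 6 members, 10 over the list alone, adjusted p = 4.61e-10, adjusted p = 0.049 with an estimated correlation) and lipid and barrier genes (0.46, 1 member, 5 over the list alone, adjusted p = 5.62e-05, adjusted p = 0.049 with an estimated correlation). The interferon list differed the other way (-1.07, 6 members, 25 over the list alone, adjusted p = 7.22e-23, adjusted p = 0.0077 with an estimated correlation). Differentiation transcription factors (0.42, adjusted p = 1.72e-07, adjusted p = 0.083 with an estimated correlation) and stress keratins and alarmins (0.38, adjusted p = 6.26e-06, adjusted p = 0.17 with an estimated correlation) had higher CSNK1A1 effects. The same held for the integrated stress response (0.22, adjusted p = 0.0098, adjusted p = 0.086 with an estimated correlation) and p53 targets (0.22, adjusted p = 0.040, adjusted p = 0.17 with an estimated correlation). Inflammatory (-0.77, adjusted p = 8.58e-11, adjusted p = 0.083 with an estimated correlation), matrix (-0.31, adjusted p = 0.00088, adjusted p = 0.083 with an estimated correlation) and RNA-binding substrate lists (-0.27, adjusted p = 0.011, adjusted p = 0.33 with an estimated correlation) had lower ones. Without CSNK1A1 hairpin A the spinous difference had adjusted p = 0.16 and the lipid and barrier difference adjusted p = 0.061 with an estimated correlation, and the RNA-binding substrate difference had adjusted p = 0.12. In that fit 19 cornified, 4 lipid and barrier, 7 transcription factor and 3 integrated stress response genes were past the threshold as higher. Lower were 14 interferon and 4 inflammatory genes. In the matrix list 3 were higher and 5 lower, against 1 and 4 over all arrays. The other 11 lists did not pass, among them mitosis (median difference -0.08, adjusted p = 0.49) and DNA replication (0.05, mean -0.02, adjusted p = 0.94). Starting levels of some differentiation genes were unlike. IVL averaged 10.19 in the CSNK1A1-set controls and 8.42 in the PRMT1-set controls, against 10.18 in the PRMT1 knockdown. KRTDAP averaged 10.15 and 8.12 in these controls, and KRT10, the other way, 10.97 and 11.11. Each set has its own controls, and the control sets themselves differed at 636 genes, so a difference between the effects is not separate from a difference between the sets. Without CSNK1A1 hairpin A the counts were 257 and 167, without its hairpin B 1721 and 2191, without controls 1 and 2 of the CSNK1A1 set 11 and 3 and then 4 and 1. They were, without controls 1 and 2 of the PRMT1 set, 11 and 4 and then 17 and 6, without PRMT1 hairpin A 55 were above, and without PRMT1 hairpin B 31 and 16. Of the 10 named genes, 3 and 1 stayed past the threshold without controls 1 and 2 of the CSNK1A1 set, 5 and 7 without those of the PRMT1 set, and 9 and 8 without PRMT1 hairpins A and B.

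The knockdowns moved many genes in common. Of the genes past the threshold, 90 rose in both, where independent lists of these sizes would share 8.83 (odds ratio 16.8, Fisher's exact test p = 8.33e-66), and 90 fell in both, against 5.36 (odds ratio 32.6, Fisher's exact test p = 6.52e-87). Opposite changes were seen for 6 genes, against 13.8 for independent lists. Genes are not independent, and both contrasts share 1 estimate of the spread per gene. The numbers for independent lists and the p-values of Fisher's exact test are therefore a description. POSTN, IGFL1, the steroid-metabolising AKR1C3, GPNMB, BLNK, the aryl hydrocarbon target CYP1A1, NEFM, SERPINB13, the tight junction gene CLDN1 and NUPR1 had the largest increases in both, ranked by the smaller of the 2. POSTN rose by 2.83 ± 0.49 (SE) and 3.46 ± 0.49, AKR1C3 by 2.57 ± 0.30 and 2.82 ± 0.30, CYP1A1 by 2.28 ± 0.29 and 2.70 ± 0.29 and CLDN1 by 2.03 ± 0.27 and 2.47 ± 0.27 with PRMT1 and CSNK1A1 knockdown. The shared increases held 7 of the 22 stress keratins and alarmins, 6 of the 18 spinous and 5 of the 33 cornified genes, and the shared decreases held 21 of the 82 genes of the mitosis and replication lists. MMP9 (2.36 ± 0.24 and -1.45 ± 0.24), the growth factor receptor FGFR3 (1.29 ± 0.15 and -0.90 ± 0.15) and NDE1 (0.80 ± 0.16 and -0.78 ± 0.16) rose with PRMT1 and fell with CSNK1A1 knockdown. PPL (-1.15 ± 0.15 and 0.92 ± 0.15) and TAS2R14 (-1.01 ± 0.15 and 0.86 ± 0.15) did the reverse. Across all genes, which are not independent replicates, the effects correlated at Pearson's r = 0.42 and Spearman's rho = 0.32. Without CSNK1A1 hairpin A 258 genes rose in both, 202 fell in both and 32 went opposite ways, and without its hairpin B the counts were 453, 494 and 163. Without control 1 or 2 of the PRMT1 set 0 and 1 genes rose in both, without PRMT1 hairpin B 6, and without control 1 or 2 of the CSNK1A1 set 8 and 9. In each of these 5 fits limma gave 0 shared decreases and 0 opposite changes, with 839 to 1349 genes lower in the PRMT1 knockdown at an unadjusted p under 0.05. Without PRMT1 hairpin A 154 genes fell in both and 9 went opposite ways.

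**Figure D5:**
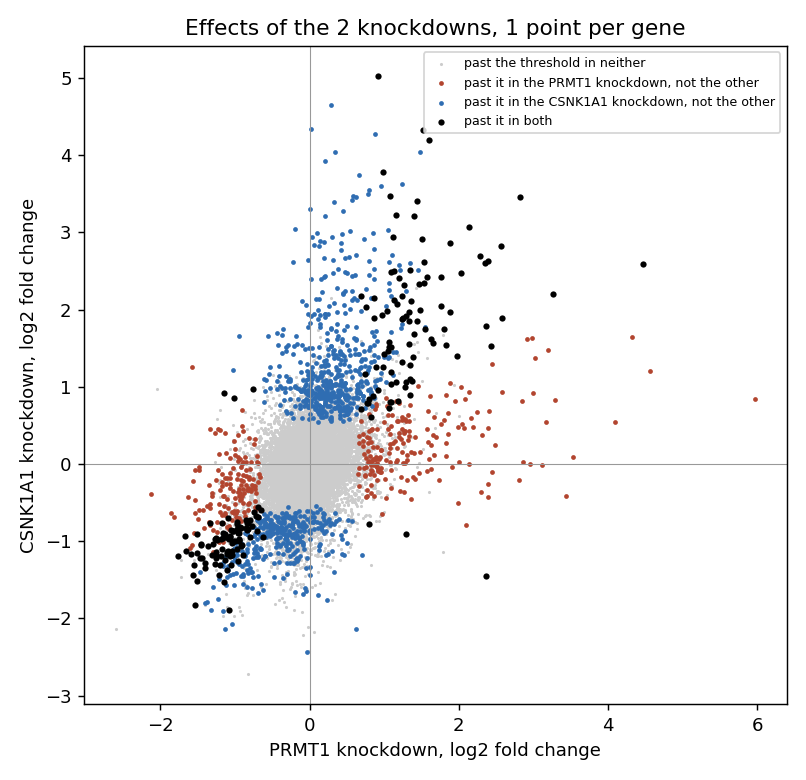
Log2 fold change of each of 19724 genes in the PRMT1 knockdown (horizontal) against the CSNK1A1 knockdown (vertical), with black points for genes past the threshold in both, red and blue for genes past it in the PRMT1 or the CSNK1A1 knockdown and grey for the rest. Black points lie mostly where both changes have the same sign, 90 higher and 90 lower, and 6 lie where the signs differ.

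The hairpins against each target were compared across genes. Across 19724 genes, the change of hairpin A over control 1 and that of hairpin B over control 2 correlated at Pearson's r = 0.71 and Spearman's rho = 0.55 for PRMT1, and at 0.53 and 0.38 for CSNK1A1. Of the 526 genes past the threshold with PRMT1 knockdown, 485 changed more with hairpin B. The control sets differed at 636 genes (260 higher and 376 lower in the CSNK1A1 set); without control 1 or 2 of the PRMT1 set the count was 64 or 45, and without control 1 or 2 of the CSNK1A1 set 42 or 30. Without CSNK1A1 hairpin A it was 3019. Poly-A spike probe sets, which report RNA added during preparation, averaged 7.71 ± 0.36 (SD, n = 4 arrays) in the PRMT1 set and 4.27 ± 0.05 (SD, n = 4) in the CSNK1A1 set. Each knockdown was compared with controls of its own set.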

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

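All tests of explanations in this part were chosen after the results were seen; the tests of the differences between the effects were planned. The effects of the knockdowns differed for 104 genes, higher with CSNK1A1, and 47 genes, lower with CSNK1A1, which a contrast of the effects picked out. Camera's test of the same contrast, at the preset correlation, picked out 11 lists, given with their median difference of log2 fold changes: spinous 1.06, cornified 1.08, lipid and barrier 0.46, differentiation transcription factors 0.42, p53 targets 0.22, stress keratins and alarmins 0.38, integrated stress response 0.22, interferon -1.07, inflammatory -0.77, matrix -0.31 and RNA-binding methylation substrates -0.27. With an estimated correlation the cornified, spinous, lipid and barrier and interferon lists stayed under 0.05, and the other 7 had adjusted p from 0.083 to 0.33. Without controls 1 and 2 of the CSNK1A1 set the gene counts were 11 and 3, then 4 and 1, without those of the PRMT1 set 11 and 4, then 17 and 6, without PRMT1 hairpins A and B 55 and 48, then 31 and 16, and without CSNK1A1 hairpins A and B 257 and 167, then 1721 and 2191. In control probe sets, which no comparison uses, the 5′ minus 3′ difference on the CSNK1A1 hairpin A array was -3.70 for GAPDH and -3.54 for ACTB, and poly-A spikes were 3.44 log2 units higher in the PRMT1 set than in the CSNK1A1 set.

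PRMT1 was low on the CSNK1A1 hairpin A array, at 8.65 against 12.004 with hairpin B. A loss of PRMT1 of at least 4-fold that follows CSNK1A1 knockdown with either hairpin is argued against by hairpin B. With hairpin B the log2 fold change of PRMT1 was -0.46 ± 0.13 (SE), so a smaller fall with both hairpins is left open. RNA of a PRMT1 knockdown sample on that array is argued against by the genes at least 4-fold higher in the PRMT1 knockdown, whose median difference between the CSNK1A1 hairpins was 0.20. Loss of signal away from the 3′ end and an effect of hairpin A on PRMT1 cannot be told apart. Of 709 genes of similar level, 2 (0.282%) were as much lower on that array, so a fall of this size was rare. The GAPDH and ACTB 5′ probe sets differed from hairpin B by -3.44 and -3.61, and PRMT1 by -3.35. Where the PRMT1 probe set lies in its transcript was not examined, so 5′ control probe sets may be an unlike measure.

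The median of the interferon list was higher in the PRMT1 knockdown and lower in the CSNK1A1 knockdown, with different members leading. The RNA quality of the hairpin A array is argued against as the source by hairpin B alone, with which the list median was -0.38. A higher interferon baseline in the CSNK1A1-set controls is argued against by the controls, whose list median was -0.78 in the CSNK1A1 set relative to the PRMT1 set. A different response to loss of each target was not tested apart from a difference in how the sets were handled, which stays open, since each knockdown belongs to 1 set.

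Genes past the threshold were shared between the knockdowns. The RNA quality of the hairpin A array is argued against as the source by the 258 genes that rose in both without it, against 38.3 for independent lists. A response to any active hairpin and a response to loss of either target cannot be told apart: the effects correlated at 0.43 without that array, and both knockdowns carry active hairpins while no hairpin against any other gene was measured.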

How the results depend on the processing

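Of the alternatives, the 4 control arrays without a block and the fits without CSNK1A1 hairpin A beside list counts were added after the data were seen; the rest were planned. Of 3580 values under alternatives, 2255 of genes kept direction and side of the threshold, 569 had the same direction but no longer passed, 19 passed newly and 6 reversed; of list shifts 437, 25, 6 and 16. Of counts and correlations 84 moved and 75 did not, and of list member counts 34 moved and 54 did not. The cause of the changes below was not tested, except that fewer arrays leave fewer degrees of freedom. A group left with 1 array is assumed to vary like the others. In the 12731 genes above the median level of all probe sets the hairpins correlated at 0.82 for PRMT1 and 0.57 for CSNK1A1. Over all 19724 genes they correlated at 0.71 and 0.53.

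Array weights gave 1107 higher and 1123 lower genes with PRMT1 knockdown and 321 and 133 with CSNK1A1 knockdown. An adjusted p under 0.10 gave 566 and 568, and 1014 and 913. A 2-fold limit gave 136 lower genes with PRMT1, and 386 and 187 with CSNK1A1. The 4 arrays of the CSNK1A1 set alone gave 156 and 24. The mean of probe sets gave 3 opposite genes, and log2 fold changes of -1.41 for PRMT1 and -1.28 for CSNK1A1 in their own knockdowns. PRMT1 passed in its own knockdown at a log2 fold change of -2.59 with array weights and with its 4 arrays alone.

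The sign or the direction of the test turned for values near 0: CSNK1A1 in the PRMT1 knockdown 0.0792 with the mean of probe sets, and in the CSNK1A1 knockdown KRT14 -0.00909 with median centring, Wnt targets 0.12, matrix genes -0.14 and immune markers -0.12 with the filter on dim genes, and matrix genes 0.0407 with fry, whose test turned.

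Leaving out 1 array at a time gave 4 to 1078 higher and 0 to 1090 lower genes with PRMT1 (limma; where 0 fell, 1020, 1004 and 839 were lower at an unadjusted p under 0.05), 140 to 2868 and 9 to 3193 with CSNK1A1, and 4 to 1721 and 1 to 2191 for the difference. Shared genes ran from 0 to 453 higher, 0 to 494 lower and 0 to 163 opposite, and the correlation of the effects from 0.34 to 0.43. The log2 fold change of PRMT1 ran from -2.67 to -2.51 in its knockdown and from -3.81 to -0.46 in the CSNK1A1 knockdown, that of CSNK1A1 in the PRMT1 knockdown from -0.0871 to 0.0240, AXIN2 with PRMT1 from -0.0110 to 0.45 and KRT14 with CSNK1A1 from -0.0146 to 0.0776. List medians ran from -0.0612 to 0.10 for melanocyte markers with PRMT1, and with CSNK1A1 from -0.11 to -0.0416 for basal, -0.0226 to 0.12 for Wnt, -0.11 to 0.12 for matrix and -0.0732 to 0.12 for endothelial genes.

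The control sets differed at 636 genes, at 30 to 64 without 1 control and at 3019 without CSNK1A1 hairpin A. With the control number as a block, over the 4 control arrays, 3369 genes differed, and 4025 with no block; same-numbered controls share only a number (correlation of deviations -0.0061).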

Other observations

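The 12 families tested, those in this part among them, and their tests were chosen after the data were seen. Some members also belong to the lists above. SERPINB3, SERPINB4 and SERPINB13 are among the alarmins, and KLK7, KLK11 and KLK13 among the cornified genes. The kinesin genes KIF2C, KIF4A, KIF11, KIF14, KIF20A and KIF23 are among the mitosis genes. The family p-values are therefore a description and not separate evidence. In the 55 measured core and linker histone genes, 5 passed the threshold as higher in both knockdowns, with log2 fold changes in the PRMT1 and CSNK1A1 knockdown of 1.88 ± 0.21 and 2.86 ± 0.21 (SE) for H2AC6, 1.77 ± 0.19 and 2.05 ± 0.19 for H2BC21, 1.53 ± 0.20 and 2.35 ± 0.20 for H2BC5, 1.33 ± 0.18 and 1.56 ± 0.18 for H2BC12 and 1.09 ± 0.19 and 2.48 ± 0.19 for H2BC4. With CSNK1A1 knockdown 8 rose in all, H4C8 most (3.42 ± 0.24), and H2AX fell (-1.14 ± 0.23). As a family histones did not pass in either knockdown (adjusted p = 0.56 and 0.15) over all arrays. Without CSNK1A1 hairpin A the family passed in the CSNK1A1 knockdown (adjusted p = 0.0089, 13 genes higher). Over all arrays histones had adjusted p = 0.73 with PRMT1 and adjusted p = 0.30 with CSNK1A1 knockdown with an estimated correlation. The immunoproteasome subunits PSMB8 (-1.40 ± 0.28) and PSMB9 (-2.14 ± 0.16) fell with CSNK1A1 knockdown, and the 37 proteasome genes had a median of -0.52 (adjusted p = 7.51e-08, adjusted p = 0.30 with an estimated correlation), or -0.15 without hairpin A.

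With CSNK1A1 knockdown 6 of 29 aldo-keto reductase and aldehyde dehydrogenase genes rose (adjusted p = 0.0016, adjusted p = 0.27 with an estimated correlation), among them ALDH3B2 (2.87 ± 0.21), AKR1C2 (2.71 ± 0.31) and AKR1C1 (2.45 ± 0.20), and AKR1C3 and AKR1B10 rose in both knockdowns. Of 15 kallikreins, the proteases that shed cornified cells, 4 rose (adjusted p = 0.032, adjusted p = 0.27 with an estimated correlation), or 7 without hairpin A (adjusted p = 0.00014), with KLK7 (2.79 ± 0.33), KLK11 (2.40 ± 0.20) and KLK6 (2.23 ± 0.18). Of 11 serpin B genes 4 rose with CSNK1A1 (adjusted p = 0.00016, adjusted p = 0.25 with an estimated correlation) and 2, or 4 without CSNK1A1 hairpin A, with PRMT1 knockdown (adjusted p = 0.019, adjusted p = 0.38 with an estimated correlation), and SERPINB3 rose by 3.40 ± 0.21 and 1.44 ± 0.21. RAB proteins (57 genes, median 0.10) and kinesins (38 genes, median -0.12) had adjusted p = 0.019 each with PRMT1 knockdown, and adjusted p = 0.38 and 0.47 with an estimated correlation. Cytochrome P450 enzymes (47 genes, median 0.15) had adjusted p = 0.0087 with CSNK1A1 knockdown and adjusted p = 0.27 with an estimated correlation. Marker levels of other cell types over all arrays had medians of 4.78 for melanocytes, 6.10 for fibroblasts, 4.72 for endothelium and 4.48 for immune cells. The median of all probe sets was 5.27. Marker values are of the brightest probe set per gene, so the measures are unlike and do not show whether a cell type was present.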
